A study of Mus musculus with 8 samples.

How the data were processed

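Messenger RNA was sequenced from mouse retinas at postnatal day 5, with 4 libraries labelled wild type (WT) and 4 labelled C3 KO. C3 is the central protein of the complement cascade, and a C3 KO animal carries a targeted C3 gene. Per the labels' protocols, retinas were dissected in cold buffer, the embryonic hyaloid vessels were removed, poly(A) RNA was selected and directional libraries were made with an NEBNext Ultra II kit. The submitters' processing notes name STAR and HTSeq without versions, and the mouse builds mm9 and NCBIM37. Whether the counting used the strand is not given in the sources used here, so a gene cannot be told apart from an overlapping antisense gene in these values. The number of animals behind each library is not given either, and p-values of single genes therefore measure the spread between these libraries. Tests that count genes take genes as their units, so their p-values do not measure that spread.

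The deposited count table holds whole-number read counts per gene, without normalization. It lists 16109 genes, each with at least 15 reads in at least 1 library, and every column was matched to its sample by its label. A second deposited table holds log2 RPKM values made by the authors. Compared with the counts, those log2 values fit the logarithm of the count plus 2 reads, with a constant for each gene and library, and the largest deviation was 0.0136. They were used only as an alternative, after being turned back to a linear scale.

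Total counts ran from 16503564 to 19608824 reads per library and differed by a factor of 1.03 between the group means. At that depth 3 reads over the 4 libraries labelled C3 KO correspond to 0.0404 CPM (reads of a gene scaled to a common library total, as edgeR's cpm function gives them). Floors and intervals cover counting error only. No pair of libraries agreed within sampling noise, since the chi-square per degree of freedom within a group was at least 3.72.

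Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes passing edgeR's expression filter entered the test, 15850 in all, and 259 were left out. Libraries were scaled by TMM. The quasi-likelihood test with robust dispersion compared the 4 libraries labelled C3 KO with the 4 labelled WT, without covariates. A gene was called at a Benjamini-Hochberg adjusted p below 0.05. Fold changes are given on the log2 scale with their standard error (SE), and levels as mean CPM with the standard deviation (SD). The SE was taken from the log2 fold change and its F statistic. In simulated counts 200 genes averaging above 1 CPM were changed, and a list of ganglion cell genes was raised beside them. Run on 15769 genes for the comparison of C3 KO with WT, the procedure recovered 58% of 1.25-fold and 76% of 1.5-fold changes. It recovered 96% of 2-fold and 98% of 4-fold changes, with 18 false calls among 15555 unchanged genes. Counts were drawn independently for each gene, so these rates do not cover genes at lower counts or variation that genes share.

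Before the data were examined, 35 gene lists were fixed, covering complement, retinal cell types, vessels, signalling pathways and tissues that a dissection could carry along. A list was tested with camera at a preset correlation of 0.01 when at least 5 members were measured, which left 31 lists, and adjusted p-values were computed over those lists. Camera compares a list's genes with the other genes, and a preset correlation does not estimate how the list's genes vary together across these libraries. Camera with an estimated correlation and the directional fry test were run beside it. Counts of called members are given over all genes and adjusted over the list alone. A list score is the mean over members of log2 CPM, each member centred on the WT-labelled mean. The named genes also followed a fixed rule. They are C3, the 10 highest and 10 lowest log2 fold changes among called genes with a mean of at least 1 CPM and no overlap between the groups, and up to 4 members of each list with the smallest p. Genes named outside that rule were chosen after their values were seen, and are marked as such. Of the named genes 3 are not reported here, while list tests and counts of genes, calls and outliers include them.

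Of the 16109 symbols, 14404 matched a current gene symbol of the GRCm38 annotation, 1333 matched through an older symbol, 24 were ambiguous and 348 had no match. Because the build differs from the one in the submitters' notes, that annotation served only for chromosomes, gene classes, distances and neighbour order, and no coordinates are given. Calls within 10 Mb of C3 on chromosome 17 were compared with calls elsewhere by a 2-sided Fisher exact test. That test treats genes as independent, although they were measured in the same libraries.

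Alternatives listed before the data were examined were other scalings (RLE and upper quartile), DESeq2 1.42.0, limma-voom, other expression filters, non-robust dispersion, limma on the log2 RPKM values with pseudocounts of 1 and 0.1, the replicate number as a block, a surrogate variable from sva 3.50.0, Y-linked expression as a covariate, other thresholds, other windows around C3 and the omission of each library in turn. Covariates for the pigment epithelium score and for Y-linked expression on a linear scale, and a count of autosomal genes alone, were chosen after seeing the data. Pseudogenes, globin genes and other near-identical copies are reported as uncertain, because the treatment of shared reads is not given in the sources used here. Of the fixed lists, 4 had fewer than 5 measured members and were not tested as lists.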

Results

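Retinal messenger RNA was profiled at postnatal day 5, while the superficial vessel layer grows across the mouse retina, to compare gene expression in wild-type and complement C3 deficient animals during retinal vascular development. The series holds 4 libraries labelled WT and 4 labelled C3 KO, from C57BL/6 mice per the labels. Total counts were 19608824, 17197420, 18734762 and 16503564 reads in the libraries labelled WT replicates 1 to 4. In the libraries labelled C3 KO replicates 1 to 4 they were 19493979, 19306215, 17795644 and 17621087 reads. The 10 most abundant genes took between 2.06% and 2.18% of the counts in every library. The first principal component held 38.0% of the variance and separated the libraries labelled C3 KO from those labelled WT.

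C3, the targeted gene, was higher in the libraries labelled C3 KO than in those labelled WT, the reverse of what the label names. The libraries labelled WT replicates 1 to 4 held 52, 45, 33 and 55 C3 reads. The libraries labelled C3 KO replicates 1 to 4 held 1718, 1585, 1550 and 1419 C3 reads. The mean level was 2.59 ± 0.642 CPM (SD, n = 4) under the WT label and 84.5 ± 3.49 CPM (SD, n = 4) under the C3 KO label. This was a 32.8-fold difference, with a log2 fold change of 5.04 ± 0.10 (SE) and an edgeR adjusted p = 1.39e-20, and it was present in all 4 libraries of each label. Gene counts do not show which exons of C3 the reads cover. They therefore cannot tell labels exchanged as a whole from a transcript still made by the targeted allele. Every direction given here is that of the libraries labelled C3 KO relative to the libraries labelled WT. It rests on labels that the C3 counts put in doubt.

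The libraries also differed in sex-linked transcripts. Xist, the RNA of the inactive X chromosome in females, stood at 2441, 2369, 295 and 2195 CPM in the libraries labelled WT replicates 1 to 4, and between 1.48 and 2.65 CPM in the 4 libraries labelled C3 KO. The mean of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty was 0.448, 5.05, 75.8 and 3.71 CPM in the libraries labelled WT replicates 1 to 4, and between 74.8 and 88.2 CPM in those labelled C3 KO. Sex-linked expression thus moved with the labels, except that the library labelled WT replicate 3 carried high Y-linked counts together with Xist. WT replicates 2 and 4 also held some Y-linked reads beside Xist, with 128 and 73 reads of Ddx3y against 10 in WT replicate 1. Eif2s3y differed by a log2 fold change of 2.07 ± 1.09 (SE) with an edgeR adjusted p = 0.279, and by 4.91 with an adjusted p = 0.00284 without the library labelled WT replicate 3. Neither sex was represented by several libraries of both labels, so the comparison could not be repeated within a sex.

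**Figure D1:**
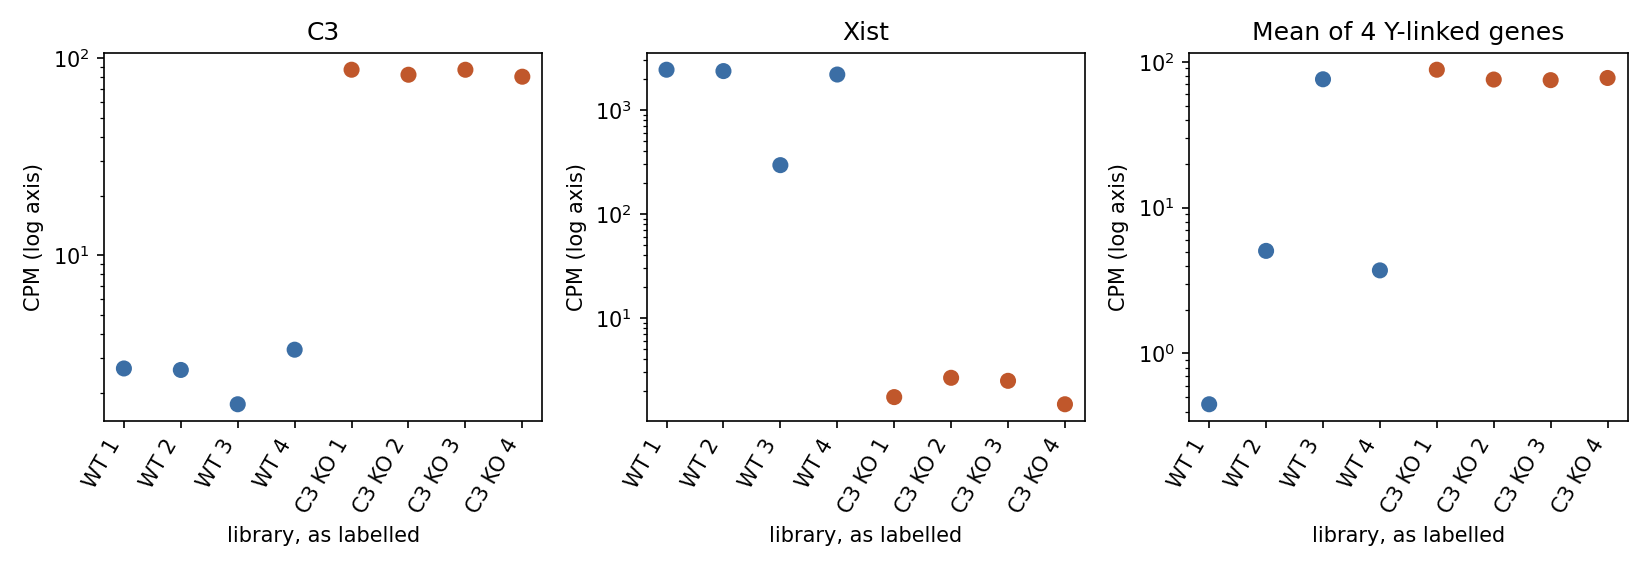
CPM on a logarithmic axis for C3, Xist and the mean of 4 Y-linked genes, 1 point per library (blue, labelled WT; orange, labelled C3 KO). C3 lies between 1.75 and 3.32 CPM in the libraries labelled WT and between 80.6 and 87.5 CPM in those labelled C3 KO, and the library labelled WT replicate 3 has 295 CPM of Xist beside 75.8 CPM of Y-linked genes.

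Across the transcriptome, 2269 of 15850 tested genes were called different, of which 1321 were higher and 948 lower in the libraries labelled C3 KO. Among them, 88 were higher and 30 lower by at least 1 on the log2 scale. The largest rise after C3 was in Rec8, a meiotic cohesin subunit, from 0.667 ± 0.566 to 9.97 ± 1.32 CPM (SD, n = 4), a log2 fold change of 3.89 ± 0.34 (SE, edgeR adjusted p = 6.64e-06). Kcnj13, a potassium channel of the pigment epithelium, was 4.98-fold higher, and Mfrp, a membrane protein of the pigment epithelium mutated in small-eye disorders, was 3.42-fold higher. Serpina3n, a secreted protease inhibitor induced in reactive glia, was 6.68-fold lower, against 8.76 ± 0.588 CPM (SD, n = 4) under the WT label (edgeR adjusted p = 3.55e-10).

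Among called genes with a mean of at least 1 CPM and no overlap between the labels, the next highest log2 fold changes in the libraries labelled C3 KO were those of Myo7a (1.98), an unconventional myosin of pigment epithelium and photoreceptors, the dicarboxylate transporter Slc13a3 (1.93), Gm13111 (1.91), the short-chain collagen Col8a1 (1.84), the fibroblast protease Fap (1.84), 3110053B16Rik (1.76) and Tmem72 (1.75). Myo7a lost its call without the library labelled WT replicate 2, C3 KO replicate 3 or C3 KO replicate 4, with edgeR adjusted p-values of 0.0567, 0.0505 and 0.056. The call of 3110053B16Rik was lost without C3 KO replicate 3 or C3 KO replicate 4, with edgeR adjusted p-values of 0.0693 and 0.0657. Gm13111 is annotated as an antisense RNA, so its reads cannot be told apart from those of an overlapping gene. The lowest values included Xist (871-fold lower, edgeR adjusted p = 0.0022, but adjusted p = 0.112 by limma-voom), Dennd1c (5.41-fold lower), Gdpd3 (3.86-fold lower) and Hddc3 (3.09-fold lower). RP23-71I22.5 had 273 reads under the WT label and 0 under the C3 KO label, and was at least 93.7-fold lower against a floor of 3 reads over the group. Rps13-ps1, a ribosomal protein pseudogene, had 1355 reads under the WT label and 1 under the C3 KO label, a CPM ratio of 1400 with an exact 95% counting interval of 250 to 55200. Its call was lost without the library labelled C3 KO replicate 2, at an edgeR adjusted p = 0.104, and by limma-voom, at an adjusted p = 0.0875. Across the libraries labelled WT, Rps13-ps1 reads followed Xist, at 1.00 to 1.07 per 100 Xist reads. The pseudogenes Gm9000 (8.73-fold lower) and Gm11968 (3.52-fold lower), and Cd1d2 (4.13-fold lower), which has a close copy in the genome, are uncertain, since how reads shared between copies were counted is not given in the sources used here. Gm13111, 3110053B16Rik, Gdpd3 and Gm11968 lost their call with Y-linked log2 CPM as a covariate. Myo7a, Gm13111, Fap, 3110053B16Rik and Rps13-ps1 lost it with 1 surrogate variable.

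Of 15850 tested genes, 2754 had no overlap between the 4 libraries of each label, where 2.86% of genes would be expected by chance. Among them were 1797 of the 2269 called genes. Calls and lack of overlap come from the same values, so this is not separate support for the calls. With Y-linked log2 CPM as a covariate 530 genes were called, and without the library labelled C3 KO replicate 4 the count was 1305. Without the library labelled WT replicate 3, which stood apart in sex-linked genes, 1703 genes were called. Of 111 named genes called, 53 lost the call with Y-linked log2 CPM as a covariate and 66 with 1 surrogate variable. These covariates correlated with the labels at 0.732 and 0.678. A call can therefore be lost because the label difference is estimated less precisely, without a smaller fold change.

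All 16 measured genes of the retinal pigment epithelium and of melanocytes had a positive log2 fold change, and 11 were called higher in the libraries labelled C3 KO (12 adjusted over the list alone), with a median of 1.04 (camera adjusted p = 9.16e-25, and adjusted p = 0.0673 with an estimated correlation). Ttr, the transthyretin carrier of thyroxine and retinol, rose from 28.4 ± 5.20 to 78.5 ± 4.07 CPM (SD, n = 4, edgeR adjusted p = 2.85e-08). Tyr, which starts melanin synthesis, rose 2.80-fold, Dct, a later melanin enzyme, 2.16-fold, and Rgr, an opsin of pigment epithelium and Mueller glia, 2.24-fold. Of 6 measured red blood cell genes 5 were lower, over all genes and adjusted over the list alone, with a median of −1.05 (camera adjusted p = 4.47e-06, and adjusted p = 0.179 with an estimated correlation). The heme synthesis enzyme Alas2 was 2.16-fold lower and the globin Hbb-b1 1.97-fold lower, the globins being uncertain because their copies are nearly identical. Neither list score overlapped between the labels. Alas2 lost its call with Y-linked log2 CPM as a covariate, and with 1 surrogate variable Alas2 and Hbb-b1 did. In these fits the log2 fold change of Alas2 was −1.13 and −1.14, against −1.11 without a covariate. That of Hbb-b1 was −1.01 with the surrogate variable, against −0.98 without it.

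**Figure D2:**
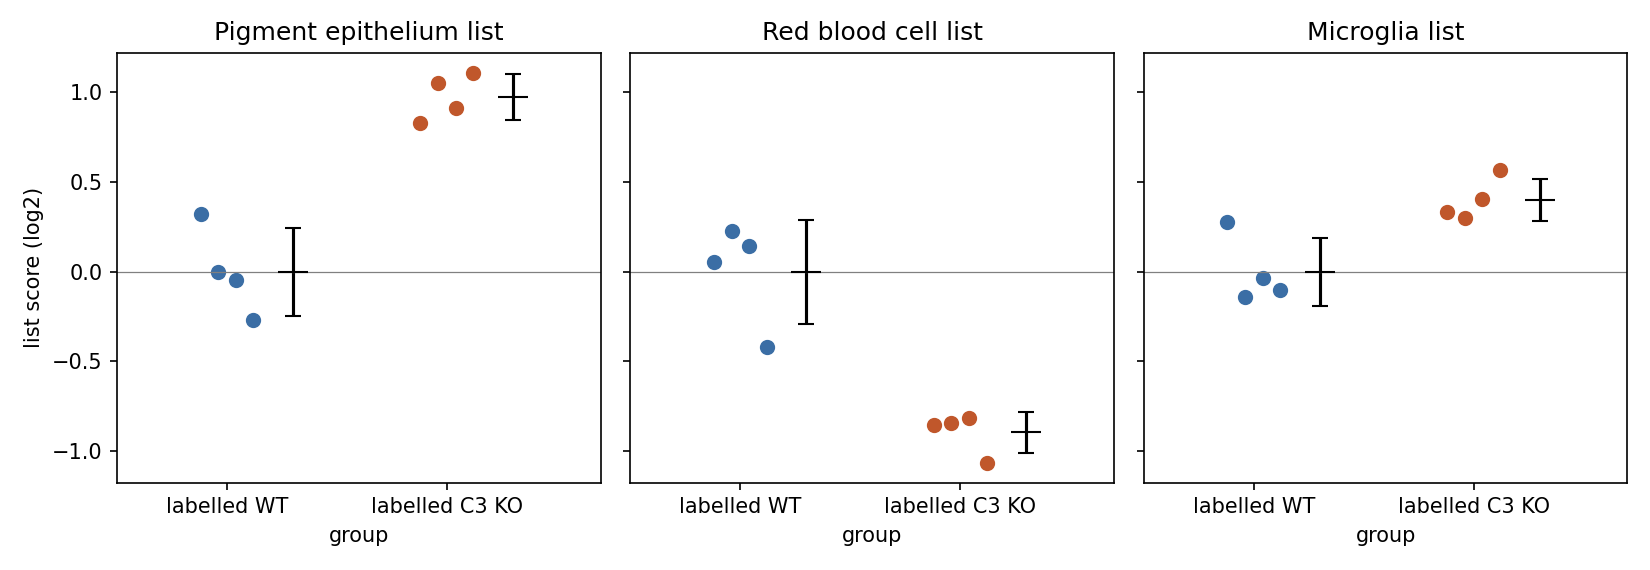
List scores per library on the log2 scale for pigment epithelium, red blood cell and microglia genes, 1 point per library, with the mean and SD of each label (n = 4) as a bar beside the points. The pigment epithelium score lies between −0.27 and 0.32 in the libraries labelled WT and between 0.83 and 1.11 in those labelled C3 KO, and the red blood cell score lies at −0.82 or below in the latter.

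Of 25 soluble complement components listed other than C3, 11 were measured. Among these 3 were called higher and none lower in the libraries labelled C3 KO (5 higher adjusted over the list alone), with a median of 0.39 (camera adjusted p = 0.000368, and adjusted p = 0.125 with an estimated correlation). The lectin Colec11 was 5.72-fold higher, a log2 fold change of 2.52, at a mean below 1 CPM under either label. It stood at 0.532 CPM in the library labelled WT replicate 3 against at most 0.0582 CPM in the other libraries labelled WT. Its log2 fold change ran from 2.08 to 5.14 when 1 library was left out, and was 0.72 with Y-linked log2 CPM as a covariate (adjusted p = 0.618). C1qb, a chain of the classical pathway's C1q, was 1.19-fold higher (edgeR adjusted p = 0.047), a call that held in only 2 of 8 fits that each left out 1 library, with adjusted p-values up to 0.154. Among 14 complement receptors and regulators 3 were higher, over all genes and adjusted over the list alone, with a median of 0.19 (camera adjusted p = 0.0381, and adjusted p = 0.373 with an estimated correlation). Clu, an extracellular chaperone that inhibits the terminal complex, rose from 45.7 ± 4.58 to 67.4 ± 4.43 CPM (SD, n = 4, edgeR adjusted p = 1.49e-05) and Susd4, a membrane regulator, rose 1.28-fold. In the libraries labelled C3 KO the pigment epithelium score was 0.83 to 1.11 against −0.27 to 0.32 under the WT label, and the microglia list had a median of 0.34 with 17 of 17 members positive. Leaving out the library labelled WT replicate 1, 2 or 3 or C3 KO replicate 3 ended the call of the receptor list, with camera adjusted p-values of 0.0608, 0.0512, 0.0596 and 0.0929. That list lost its call with Y-linked log2 CPM or 1 surrogate variable as a covariate (camera adjusted p = 0.0509 and 0.216). C1qb and Susd4 lost theirs under both, and Colec11 lost it with the surrogate variable as well.

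All 17 measured microglia markers had positive log2 fold changes and 4 were called higher under the C3 KO label (5 adjusted over the list alone), with a median of 0.34 (camera adjusted p = 2.09e-05, and adjusted p = 0.373 with an estimated correlation). Fcrls, a microglial surface receptor, rose from 9.16 ± 1.16 to 18.3 ± 1.20 CPM (SD, n = 4, edgeR adjusted p = 2.65e-06) and Csf1r, the growth factor receptor that microglia need, rose 1.42-fold. Of 11 measured genes of phagocytic developmental microglia 3 were higher (4 adjusted over the list alone), with a median of 0.25 (camera adjusted p = 0.00167, and adjusted p = 0.125 with an estimated correlation). These were Gpnmb (2.86-fold), a glycoprotein that melanocytes and pigment epithelium also make, the growth factor Igf1 (1.38-fold) and the lipoprotein lipase Lpl (1.31-fold). In the libraries labelled C3 KO the pigment epithelium score was 0.83 to 1.11 against −0.27 to 0.32 under the WT label. With 1 surrogate variable the microglia list (camera adjusted p = 0.0704) and Csf1r lost their call.

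Of 20 endothelial markers 1 was higher and none lower in the libraries labelled C3 KO, over all genes and adjusted over the list alone, with a median of 0.04 (camera adjusted p = 0.499). That gene was Tek, the angiopoietin receptor, at 9.46 ± 1.36 CPM under the WT label and 13.4 ± 2.37 CPM under the C3 KO label (SD, n = 4, edgeR adjusted p = 0.0151). Pecam1 stood at 20.2 ± 2.67 and 23.0 ± 2.12 CPM (SD, n = 4) and did not pass. Among VEGF, angiopoietin and semaphorin ligands and receptors 3 of 18 were higher (3 higher and 1 lower adjusted over the list alone), with a median of 0.08 (camera adjusted p = 0.147). The largest was Thbs1, a matrix protein that restrains angiogenesis, which rose from 16.0 ± 3.77 to 41.0 ± 3.87 CPM (SD, n = 4, edgeR adjusted p = 1.04e-05). Across WT replicates 1 to 4 Thbs1 fell in the order of the pigment epithelium score, at 21.3, 15.5, 14.4 and 12.6 CPM. The scores there were 0.32, −0.0025, −0.049 and −0.27. Under the C3 KO label the score was 0.83 to 1.11. Replicate 1 was lowest in both there, while the other replicates did not keep the order. Whether the Thbs1 reads came from pigment epithelium was not tested. Without the library labelled WT replicate 1 the VEGF, angiopoietin and semaphorin list passed, at a camera adjusted p = 0.0404. Without WT replicate 4, C3 KO replicate 3 or C3 KO replicate 4 Tek lost its call, at edgeR adjusted p-values of 0.0536, 0.0661 and 0.0558. It also lost the call on log2(RPKM + 1) (adjusted p = 0.0667), and with Y-linked log2 CPM (0.311) or 1 surrogate variable (0.376) as a covariate.

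Of 13 endothelial tip cell genes 1 was higher and 2 lower in the libraries labelled C3 KO, over all genes and adjusted over the list alone, with a median of −0.08 (camera adjusted p = 0.499). Nid2, a basement membrane nidogen, was 1.41-fold higher. The vasodilator peptide Adm (log2 fold change −0.98, edgeR adjusted p = 0.0433) and the chemokine receptor Cxcr4 (−0.34, edgeR adjusted p = 0.0487) each kept the call in only 2 of 8 fits that left out 1 library, with adjusted p-values up to 0.12 and 0.146. Norrin signalling and barrier genes had 2 lower among 19, over all genes and adjusted over the list alone, with a median of −0.05 (camera adjusted p = 0.302). These were the glucose transporter Slc2a1 (1.19-fold) and the Wnt co-receptor Lrp5 (1.24-fold). Pericyte and smooth muscle markers had 2 lower among 14, over all genes and adjusted over the list alone, with a median of 0.01, a mean of −0.03 and a camera test pointing down (adjusted p = 0.459). They were Vtn (−0.28) and Ndufa4l2 (−0.44), and each held in 3 of 8 fits that left out 1 library, with edgeR adjusted p-values up to 0.0803 and 0.0798. Basement membrane components had 5 of 17 higher, over all genes and adjusted over the list alone, with a median of 0.09 (camera adjusted p = 0.0148, and adjusted p = 0.457 with an estimated correlation). Lamb1, a laminin chain, rose from 46.8 ± 3.85 to 62.3 ± 3.22 CPM (SD, n = 4, edgeR adjusted p = 0.000196). In the libraries labelled C3 KO the pigment epithelium score was 0.83 to 1.11 against −0.27 to 0.32 under the WT label, and the fibroblast and sclera score was 0.32 to 0.55 against −0.14 to 0.08. The basement membrane list lost its call without the library labelled WT replicate 2 or C3 KO replicate 3, at camera adjusted p-values of 0.0713 and 0.0928. Adm, Cxcr4 and Ndufa4l2 lost their call on log2(RPKM + 1). These 3 genes, Nid2 and Vtn lost it with Y-linked log2 CPM or 1 surrogate variable as a covariate. Lrp5 lost it with the former, and Slc2a1 and the basement membrane list (camera adjusted p = 0.556) with the latter.

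Among 20 hypoxia-inducible genes 8 fell and 1 rose in the libraries labelled C3 KO (9 and 1 adjusted over the list alone), with a median of −0.18 (camera adjusted p = 0.00147, and adjusted p = 0.364 with an estimated correlation). Ldha, which turns pyruvate into lactate, fell from 1549 ± 52.1 to 1333 ± 42.1 CPM (SD, n = 4, edgeR adjusted p = 0.0038), Slc2a1 was 1.19-fold lower and Egln3, an oxygen-sensing hydroxylase, 1.81-fold lower. Notch pathway genes had 8 lower and 1 higher among 17 (10 and 1 adjusted over the list alone), with a median of −0.27 (camera adjusted p = 9.06e-05, and adjusted p = 0.364 with an estimated correlation). The ligand Dll1 was 1.43-fold lower, the target Hey2 1.47-fold lower and the glycosyltransferase Lfng 1.37-fold lower, while the ligand Jag2 was 1.33-fold higher. In the same libraries the red blood cell score was −1.07 to −0.82 against −0.42 to 0.23 under the WT label. There the pigment epithelium score was 0.83 to 1.11 against −0.27 to 0.32. Dll1, Hey2, Lfng, Ldha and Egln3 lost their call with Y-linked log2 CPM as a covariate, at adjusted p-values of 0.0877, 0.0822 and 0.0615 for the first 3. Dll1 (adjusted p = 0.172), Hey2 (0.292), Jag2, Slc2a1, Egln3 and the hypoxia list (camera adjusted p = 0.0681) lost it with 1 surrogate variable.

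Of 18 retinal progenitor markers 10 fell and 2 rose in the libraries labelled C3 KO (13 and 2 adjusted over the list alone), with a median of −0.42 (camera adjusted p = 1.36e-06, and adjusted p = 0.373 with an estimated correlation). Neurog2, a proneural transcription factor, was 1.60-fold lower and the eye-field factor Rax 1.32-fold lower. Pax6, which amacrine and ganglion cells also express, was 1.20-fold higher. Cell cycle genes had 24 of 25 negative log2 fold changes, of which 3 were called over all genes and 15 adjusted over the list alone, with a median of −0.29 (camera adjusted p = 4.15e-06, and adjusted p = 0.394 with an estimated correlation). E2f1, a driver of S-phase entry, was 1.51-fold lower. In the libraries labelled C3 KO the pigment epithelium score was 0.83 to 1.11 against −0.27 to 0.32 under the WT label. Pax6 lost its call with Y-linked log2 CPM as a covariate, and with 1 surrogate variable Neurog2 and E2f1 did.

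All 16 ganglion cell markers had positive log2 fold changes and 11 were called higher in the libraries labelled C3 KO (13 adjusted over the list alone), with a median of 0.28 (camera adjusted p = 4.83e-07, and adjusted p = 0.373 with an estimated correlation). Pou4f2, a ganglion cell transcription factor, rose from 41.3 ± 6.14 to 55.8 ± 5.10 CPM (SD, n = 4, edgeR adjusted p = 0.00391), and the growth cone protein Gap43 and the transcription factor Isl1 rose 1.27-fold each. Synaptic genes had 7 higher and 2 lower among 19 (9 and 3 adjusted over the list alone), with a median of 0.13 (camera adjusted p = 0.00186, and adjusted p = 0.401 with an estimated correlation), among them the scaffold Shank1 (1.45-fold higher) and the glutamate receptor subunits Gria1 (1.27-fold) and Gria2 (1.31-fold). Amacrine and horizontal cell markers had 3 higher among 16 (4 higher and 2 lower adjusted over the list alone), with a median of 0.08 (camera adjusted p = 0.434). Calb2 and Gad1, markers of inhibitory amacrine cells, were 1.24-fold and 1.26-fold higher under the C3 KO label. There the pigment epithelium score was 0.83 to 1.11 against −0.27 to 0.32 under the WT label. Pou4f2 lost its call with Y-linked log2 CPM as a covariate. Pou4f2, Gap43, Isl1, Calb2, Gad1 and the synapse list (camera adjusted p = 0.264) lost it with 1 surrogate variable.

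Photoreceptor markers had 6 lower among 25 in the libraries labelled C3 KO (11 lower and 1 higher adjusted over the list alone), with a median of −0.12 (camera adjusted p = 0.00369, and adjusted p = 0.506 with an estimated correlation). The log2 fold change was −0.38 for Neurod1, −0.36 for Prdm1, which holds cells in the photoreceptor fate, and −0.40 for the rod transducin Gnat1. Bipolar markers had 5 lower and 1 higher among 13, over all genes and adjusted over the list alone, with a median of −0.24 (camera adjusted p = 0.0112, and adjusted p = 0.385 with an estimated correlation). Vsx1 fell from 5.53 ± 1.16 to 2.16 ± 1.01 CPM (SD, n = 4, edgeR adjusted p = 0.00224), while Trpm1, which melanocytes also express, was 1.68-fold higher. Mueller glia markers had 4 lower among 12 (5 adjusted over the list alone), with a median of −0.25 (camera adjusted p = 0.00254, and adjusted p = 0.385 with an estimated correlation), among them the potassium channel Kcnj10 (log2 fold change −0.59) and the transcription factor Sox9 (−0.45). Retinal astrocyte markers had 3 higher and 2 lower among 11 (7 and 2 adjusted over the list alone), with a median of 0.37 (camera adjusted p = 0.0267, and adjusted p = 0.403 with an estimated correlation). The gap junction protein Gja1 was 1.75-fold, Gfap 1.49-fold and Pdgfra 1.33-fold higher. In the libraries labelled C3 KO the pigment epithelium score was 0.83 to 1.11 against −0.27 to 0.32 under the WT label. Without the library labelled C3 KO replicate 3 the photoreceptor list did not pass (camera adjusted p = 0.0811), and without WT replicate 3 or C3 KO replicate 1 the astrocyte list did not (0.0538 and 0.0738). Gnat1, Vsx1, Trpm1, Kcnj10, Sox9 and Gfap lost their call with Y-linked log2 CPM or 1 surrogate variable as a covariate, as did the photoreceptor list (camera adjusted p = 0.0509 and 0.116). Neurod1 lost it with the former. The bipolar, Mueller glia and astrocyte lists lost it with the latter (camera adjusted p = 0.168, 0.268 and 0.426). With Y-linked log2 CPM the log2 fold change of Sox9 was −0.55 against −0.45 without a covariate, and that of Gfap 0.71 against 0.58. Gnat1, Vsx1 and Kcnj10 stood at −0.46, −1.37 and −0.58 against −0.40, −1.36 and −0.59, and Trpm1 at 0.49 against 0.75. With the surrogate variable Sox9, Gfap and Gnat1 stood at −0.47, 0.33 and −0.46. Vsx1, Kcnj10 and Trpm1 stood at −1.02, −0.37 and 0.59.

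**Figure D3:**
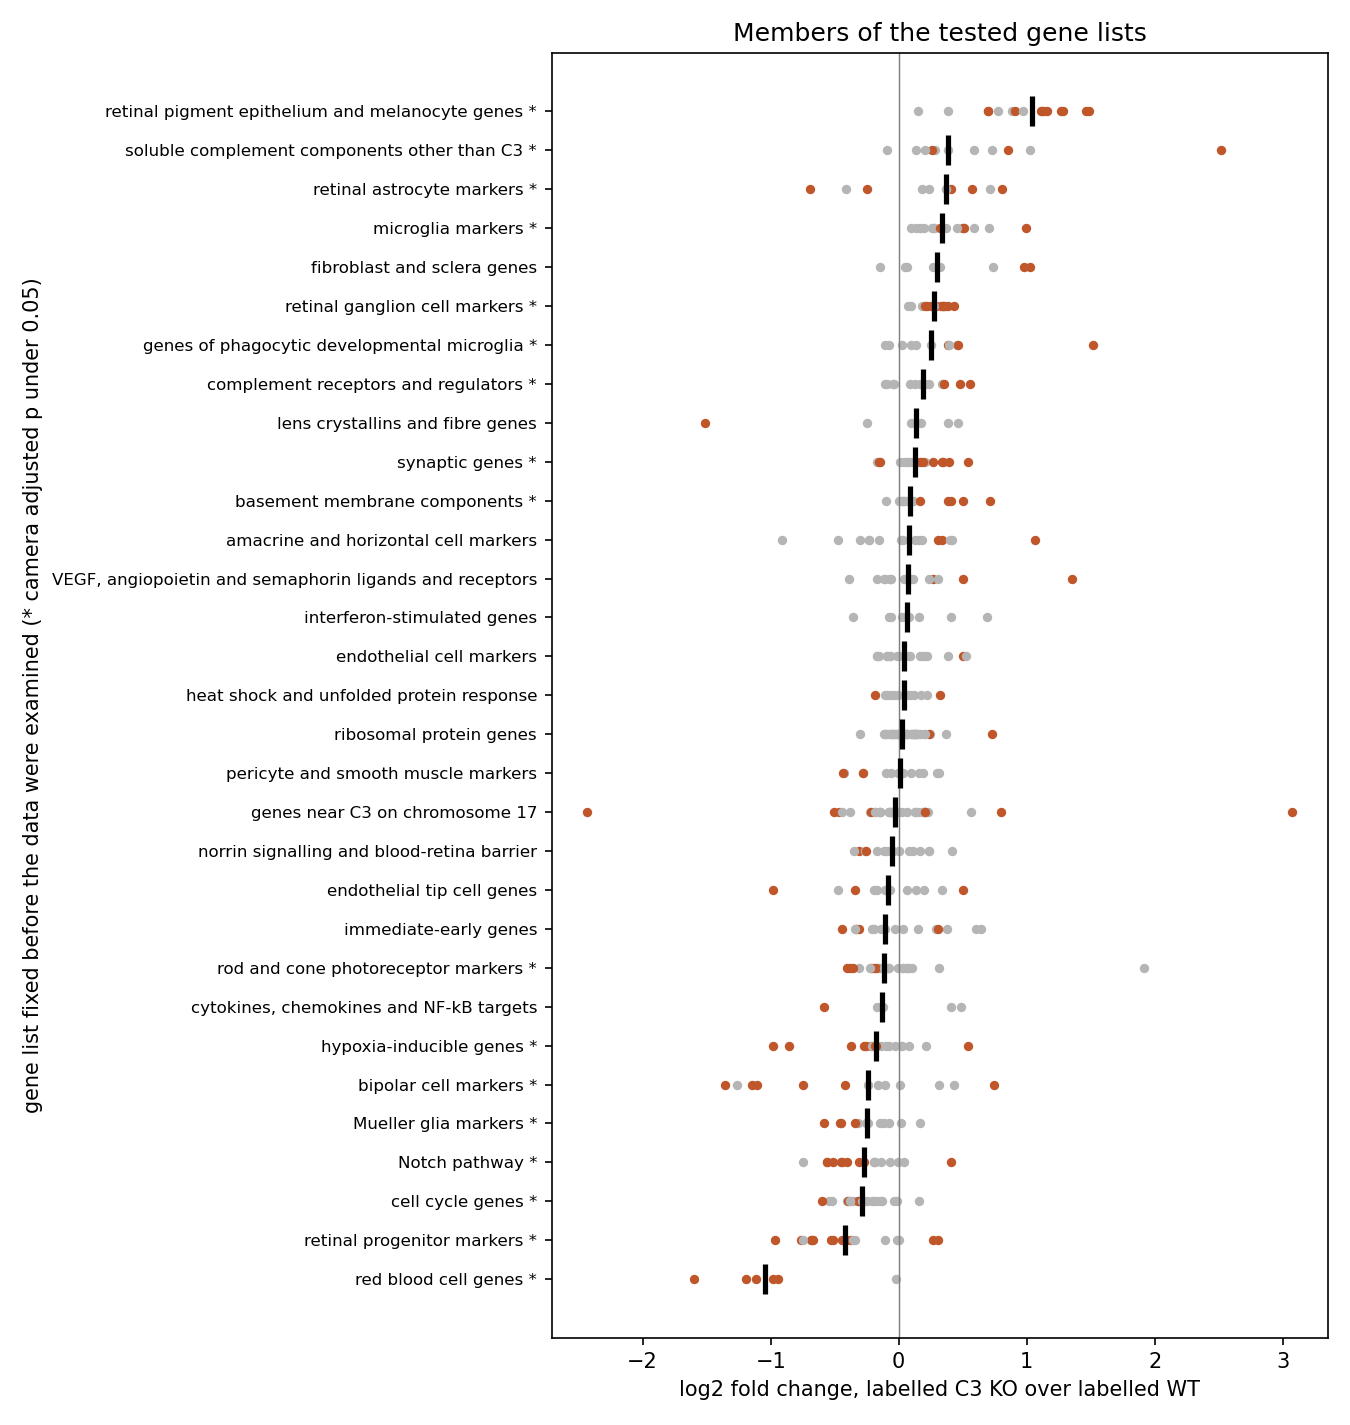
Log2 fold changes of the measured members of the 31 tested gene lists, labelled C3 KO over labelled WT, 1 point per gene (orange, edgeR adjusted p below 0.05; grey, not called), with the list median as a black bar and an asterisk for a camera adjusted p below 0.05. The pigment epithelium list has the highest median, 1.04, and the red blood cell list the lowest, −1.05.

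Of 21 interferon-stimulated genes listed 10 were measured, and none was called over all genes or adjusted over the list alone (median 0.07, camera adjusted p = 0.86). Of 20 cytokine and NF-kB genes listed 6 were measured, with a median of −0.13 (camera adjusted p = 0.45). Among them 1 was lower, over all genes and adjusted over the list alone, namely the NF-kB inhibitor Tnfaip3 (log2 fold change −0.59). These tests cover only the measured members. Immediate-early genes had 3 lower and 1 higher among 17, over all genes and adjusted over the list alone, with a median of −0.11 (camera adjusted p = 0.186, fry adjusted p = 0.0256), and Jun was 1.36-fold and Btg2 1.24-fold lower in the libraries labelled C3 KO. Heat shock and unfolded protein response genes had 1 higher and 1 lower among 13, over all genes and adjusted over the list alone (median 0.04, camera adjusted p = 0.894), namely Asns (0.32) and Hsph1 (−0.19). Ribosomal protein genes had 2 higher among 51 (1 adjusted over the list alone), with a median of 0.03 (camera adjusted p = 0.296). Fibroblast and sclera genes had 2 higher among 8, over all genes and adjusted over the list alone, with a median of 0.30 (camera adjusted p = 0.098, fry adjusted p = 0.00847), the collagen Col1a2 (2.03-fold) and the proteoglycan Ogn (1.97-fold). Of 23 lens genes listed 6 were measured and 1 was lower (1 higher and 1 lower adjusted over the list alone), with a median of 0.13, a mean of −0.11 and a camera adjusted p = 0.94. The lists of perivascular macrophages, with 3 measured genes, and of extraocular muscle, with 4, held no call over all genes or adjusted over the list alone, with medians of 0.43 and −0.22. The lists of blood leukocytes and of mitochondrially encoded RNAs had 0 measured genes. Tnfaip3, Asns, Hsph1 and Ogn lost their call with Y-linked log2 CPM or 1 surrogate variable as a covariate. Col1a2 lost it with the latter and on log2(RPKM + 1).

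In all, 17 of the 31 tested lists passed camera with the preset correlation, and 0 passed with an estimated correlation (lowest adjusted p = 0.0673), where 4 had an unadjusted p below 0.05. By fry, which asks whether a list's genes move one way without comparing them with other genes, 10 lists passed, 8 of them among the 17. The other 2 were the fibroblast and sclera and the immediate-early lists. Lists that passed camera but not fry were ganglion cell (fry adjusted p = 0.0505), progenitor (0.0635), synapse (0.0635) and Mueller glia (0.0814). The basement membrane, astrocyte, cell cycle and bipolar lists (0.0842 each) and the photoreceptor list (0.231) did not pass fry either. With the pigment epithelium score as a covariate, chosen after seeing the data and correlated at 0.944 with the labels, 16 genes were called and 15 list medians changed sign, among them progenitor (0.35), cell cycle (0.48), ganglion cell (−0.12) and microglia (−0.12) genes.

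Genes next to C3 on chromosome 17 were examined because a targeted allele can carry flanking DNA of another strain. Close to C3, Slc25a41, a mitochondrial carrier gene, was 8.42-fold higher in the libraries labelled C3 KO, at 0.162 ± 0.0893 against 1.45 ± 0.371 CPM (SD, n = 4, edgeR adjusted p = 7.07e-05). On the same side of C3, Dennd1c was 5.41-fold lower, Tnfsf9, a ligand of the TNF family, 1.42-fold lower and Khsrp, an RNA decay factor, 1.38-fold lower. These lie 7, 4, 1 and 8 tested genes from C3 in the GRCm38 order, and the 6 tested genes nearest to C3 on its other side held no call. Farther on that side, the gene 7 away was called lower (log2 fold change −0.40, edgeR adjusted p = 0.0118). The gene 14 away was called higher (0.20, edgeR adjusted p = 0.00349). On the first side the genes 6 and 15 away were called too, the nearer lower and the farther higher. Of 39 measured members of the list of C3 neighbours 4 were higher and 5 lower (5 and 5 adjusted over the list alone), with a median of −0.03, a mean of 0.0036 and a camera test pointing down (adjusted p = 0.252). Within 10 Mb of C3, 21 of 116 tested genes were called, or 18.1%, against 2213 of 15380 elsewhere, or 14.4%, an odds ratio of 1.32 (2-sided Fisher exact p = 0.287). Within 5 Mb the odds ratio was 1.87 (2-sided Fisher exact p = 0.0352). Tnfsf9 lost its call with Y-linked log2 CPM or 1 surrogate variable as a covariate, and the odds ratio within 10 Mb was 2.18 with the latter (2-sided Fisher exact p = 0.0507).

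**Figure D4:**
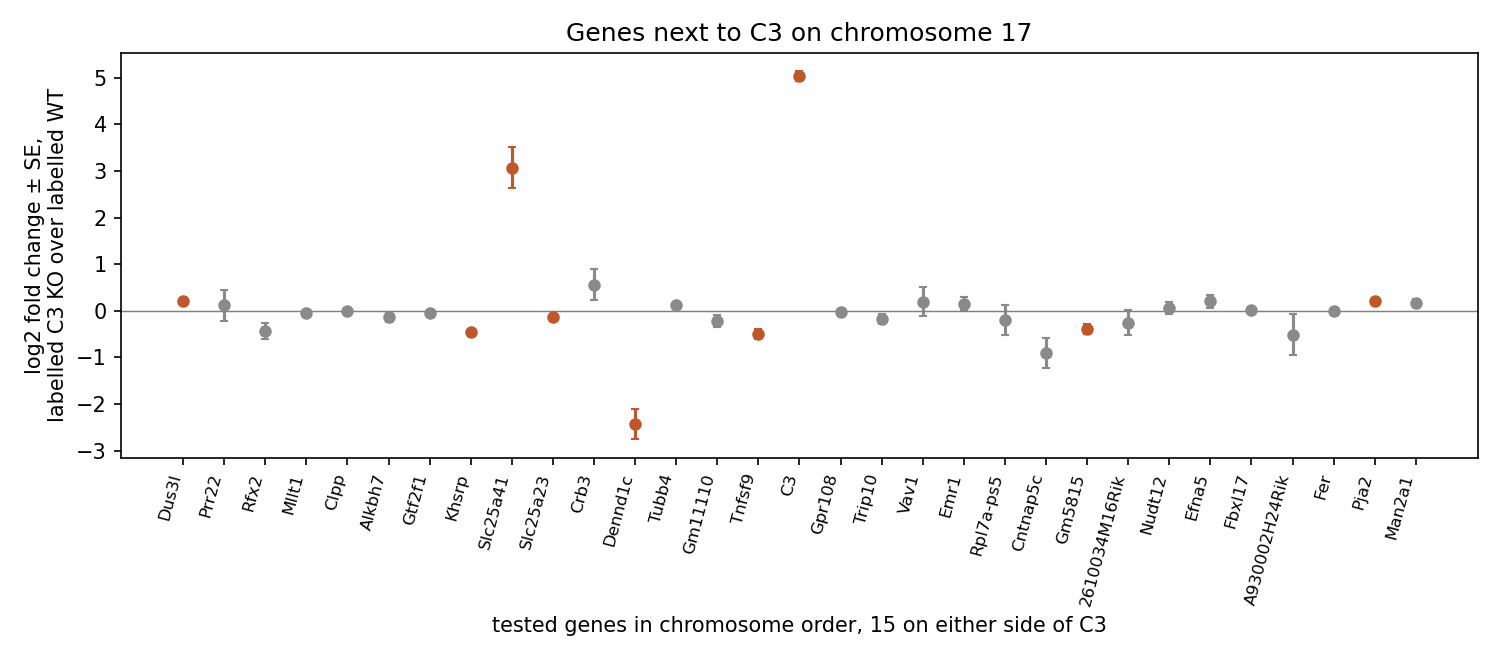
Log2 fold change with its SE, labelled C3 KO over labelled WT, for C3 and the 15 tested genes on either side of it on chromosome 17 in GRCm38 order (orange, edgeR adjusted p below 0.05; grey, not called). C3 stands at 5.04, Slc25a41 at 3.07 and Dennd1c at −2.44.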

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

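The tests of the C3 pattern were chosen after its result was seen, and the tests of the other patterns before their results were seen.

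C3 was 32.8-fold higher in the libraries labelled C3 KO, the reverse of what the label names. More pigment epithelium or microglia does not account for it, since the higher of those 2 list medians was 1.04 against 5.04 for C3, and single mislabelled libraries do not either, since the lowest C3 level labelled C3 KO was 24.3 times the highest labelled WT. Labels exchanged as a whole and a transcript still made from the targeted allele each need only a ratio above 1, and at 24.3 they cannot be told apart from gene counts, which do not show the exons covered. A biological effect of the genotype on its own locus stays open and untested.

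Of 16 pigment epithelium genes 11 were called higher in the libraries labelled C3 KO, with a list median of 1.04. The median with Y-linked log2 CPM as a covariate was 1.17, a ratio of 1.125 to the value without it, but this leaves the sex makeup of the labels open, because WT replicate 3 is the only library labelled WT with high Y-linked counts. Within labels the list's members rose and fell together across libraries, with a mean residual correlation of 0.298 against a median of −0.0028 and a 95th percentile of 0.0787 over 10000 random lists of matched expression. A varying amount of pigment epithelium left on the retinas would give this. But the random lists hold unrelated genes, and markers of a single cell type can move together for other reasons. The test therefore does not single out that cause, and an effect of the genotype on pigment genes stays open.

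The count of 2269 called genes was compared with other splits of the 8 libraries. Of 35 splits into 4 and 4, only the real one (1 of 35) reached that count and the highest other gave 10. Every other split mixes both labels within each group of 4, so the label difference adds to the spread there and can lower its count. A share below 1 of 35 also cannot be reached. The count thus belongs to the split along the labels, but the splits do not decide on chance for it. For gene lists 2 of 35 splits gave 17 lists, the real one and a split that joined the library labelled WT replicate 1 with C3 KO replicates 1, 3 and 4. That split still keeps most libraries of each label apart, so its lists carry much of the label difference. The splits therefore do not decide on chance for that number, and chance cannot be excluded. Over 2138 called autosomal genes the fold changes with Y-linked log2 CPM as a covariate had a slope of 0.995 on those without it, but that rests on WT replicate 3 as well, and the calls fell to 530, so sex cannot be told apart from the labels. Sex, genotype, substrain, dissection and other differences that follow the labels stay open.

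Among 366 groups of 4 libraries tested for a value far from the other 3, 21 stood apart, against 18.3 expected by chance. In the library labelled WT replicate 3, Myo7a stood at 32.8 CPM against at most 13.7 in the other WT-labelled libraries, Colec11 at 0.532 CPM against at most 0.0582, and Xist at 295 CPM against 2195 to 2441. The same library had Eif2s3y at 81.3, Kdm5d at 59.8 and Uty at 49.6 CPM, where the others had at most 5.18, 4.72 and 2.85.

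In the library labelled WT replicate 1, Mcam was at 36.8 CPM and E2f1 at 21.0 CPM, each below the others, and Ttr at 36.2 CPM, above the others. In WT replicate 4, Egln3 was at 7.85 CPM, above the others, and Alas2 at 2.23 CPM, below them, and the pericyte and smooth muscle score was −0.25. The bipolar score of WT replicate 2 was 0.23, above the others.

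In the library labelled C3 KO replicate 2, Tnfaip3 was at 8.69 CPM, above the others, Pax6 at 562 CPM, below them, and the tip cell score was −0.39. Rps13-ps1 was at 0.052 CPM there, a single read, against 0 in the other 3. Plk1 was at 12.3 CPM in C3 KO replicate 3, and in C3 KO replicate 4 Acta1 was at 3.75 CPM, each above the others, and the red blood cell score was −1.07, below them.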

How the results depend on the processing

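The covariates for pigment epithelium and for Y-linked linear CPM were chosen after seeing the data. C3 stayed higher in the libraries labelled C3 KO under all alternatives run, with log2 fold changes from 3.52 on log2(RPKM + 1) to 5.48. Counts of called genes were within 1.5 times 2269 under other scalings, DESeq2 (2492), limma-voom (2211), other filters and non-robust dispersion. Replicate numbers did not pair the libraries, since same-numbered deviations correlated at −0.06, 0.09, 0.004 and −0.06, and not every library correlated best with its own number. With the replicate number as a block 2400 genes were called, 1415 higher and 985 lower, C3 stood at 5.04, the odds ratio near C3 was 1.16 and the receptor list's camera adjusted p was 0.0509, while 6 named genes lost and 3 gained a call. With 1 surrogate variable 66 named genes lost the call, with Y-linked log2 CPM 53, and by limma-voom 4. On log2(RPKM + 1), log2(RPKM + 0.1) and log2(RPKM + 1) without a filter 16, 15 and 16 lost it, among them Tek (adjusted p = 0.0667), Col1a2 (0.0587) and Adm (0.0524) on the first. Causes of the changes given next were not tested, except that thresholds and omitted libraries change what is counted. Of 111 named genes called, 86 kept the call whichever library was left out. Depth limits genes near 1 CPM, where a few reads decide a fold change.

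On log2(RPKM + 1), log2(RPKM + 0.1) and log2(RPKM + 1) without a filter 1490, 1479 and 1461 genes were called, of which 819, 808 and 807 were higher. With 1 surrogate variable there were 453, 280 higher and 173 lower, and 8 lists passed. With Y-linked log2 CPM as a covariate there were 530, 349 higher and 181 lower, 505 of them shared with the 2269, and with Y-linked linear CPM 111, 72 higher and 39 lower, and 10 lists. Under that linear covariate 1 of the 2269 genes changed sign. With the pigment epithelium score as a covariate 16 genes were called, 5 higher and 11 lower, 541 of the 2269 genes and 48 of 151 named genes changed sign, and C3 stood at 5.43. That score correlates at 0.944 with the labels, so little of the label difference is left to estimate. Autosomal genes alone gave 2138.

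At an adjusted p below 0.1, 1457 genes were lower. Below 0.01, 1025 were called, 645 higher and 380 lower, and with an absolute log2 fold change of at least 1, 118, 88 higher and 30 lower. Leaving out 1 library at a time gave 1305 (without C3 KO replicate 4) to 2543 called genes, 761 to 1516 higher and 544 to 1027 lower. The higher count was 861 without WT replicate 2 and 848 without C3 KO replicate 3. The same omissions gave C3 values of 4.88 to 5.16, odds ratios of 1.08 to 1.56 and 14 to 17 lists. An estimated correlation left 0 lists and fry gave 10. Within 5 Mb of C3 the odds ratio was 1.87 (exact p = 0.0352) and within 20 Mb 1.35 (exact p = 0.0837). With 1 surrogate variable the odds ratio within 10 Mb was 2.18 (exact p = 0.0507).

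Among named genes and lists, apart from the covariates chosen after seeing the data, directions that reversed (for a list, that of the set test) belonged to values that passed no test before or after. With 1 surrogate variable these included Itgam (−0.018), Tgfb1 (−0.12), Crybb1 (0.26), Actc1 (0.42), Mylpf (0.23) and the endothelial list (median −0.068). With Y-linked log2 CPM they were Oasl2 (0.11), Mylpf (0.0063), Uty (−0.16) and the lens list (0.20), and with linear CPM the lens (0.26) and ribosomal protein (−0.040) lists. A mean of at least 1 CPM turned the interferon list (0.041). The pigment epithelium covariate turned 15 list medians: endothelial −0.40, tip cell 0.15, hypoxia 0.14, Notch 0.30, basement membrane −0.036, astrocyte −0.11, Mueller glia 0.26, microglia −0.12, cytokine 0.084, progenitor 0.35, cell cycle 0.48, ganglion cell −0.12, synapse −0.14, stress −0.12 and ribosomal protein −0.017. Of these the endothelial, Notch, Mueller glia, progenitor and cell cycle lists passed camera at the preset correlation in the new direction, at adjusted p = 0.00499, 0.00746, 0.00342, 2.15e-06 and 9.7e-08. That covariate was chosen after seeing the data and correlates at 0.944 with the labels. Little of the label difference is left to estimate in that fit, so these p-values do not establish a direction for those lists. Leaving out 1 library turned Mylpf (−0.26 to 0.015 over all omissions, positive without WT replicate 2) and the set test of the interferon (medians 0.016 to 0.099 over all omissions), stress (−0.0067 to 0.075) and lens (0.020 to 0.17) lists.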

Other observations

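The genes named in the next 3 paragraphs were chosen after their values were seen. On chromosome 12 the maternally expressed RNAs Meg3, Rian and Mirg were higher in the libraries labelled C3 KO, with log2 fold changes of 0.80 ± 0.08, 0.54 ± 0.05 and 0.66 ± 0.15 (SE, n = 4), and edgeR adjusted p-values of 3.66e-05, 6.69e-07 and 0.00436. Meg3 rose from 1190 ± 114 to 2078 ± 252 CPM (SD, n = 4). The paternally expressed Dlk1 was lower, from 4.90 ± 1.04 to 2.94 ± 0.399 CPM (SD, n = 4), a log2 fold change of −0.74 ± 0.19 (SE, edgeR adjusted p = 0.0113). Its neighbour Begain was higher, with a log2 fold change of 0.45 (edgeR adjusted p = 0.000243). On chromosome 2 the voltage-gated sodium channel genes Scn1a (0.37), Scn2a1 (0.35), Scn3a (0.41), Scn7a (0.69) and Scn9a (0.63), which lie close together, were called higher under the C3 KO label.

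Col8a2, the partner chain of the collagen Col8a1, was 3.07-fold higher in the libraries labelled C3 KO (edgeR adjusted p = 0.00082), Col4a3 3.13-fold higher (adjusted p = 2.45e-05) and Col4a4, its neighbour in the genome, 2.26-fold higher (adjusted p = 0.0016). The pigment cell exchanger Slc24a5 was 3.19-fold higher, the chloride channel protein Clic6 2.95-fold higher and the carbonic anhydrase Car12 2.97-fold higher.

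Ide and Fgfbp3 on chromosome 19, which lie in a segment known to vary in copy number among C57BL/6J mice, were 1.90-fold and 2.23-fold higher in the libraries labelled C3 KO (edgeR adjusted p = 9.39e-12 and 5.79e-07). Btaf1, from the same stretch of the chromosome, was 1.33-fold higher, while Cpeb3 had a log2 fold change of 0.01 ± 0.08 (SE). Gabra2, which carries a known C57BL/6J variant that lowers its expression, was 2.11-fold lower under the C3 KO label, from 55.3 ± 2.54 to 26.2 ± 1.26 CPM (SD, n = 4, edgeR adjusted p = 1.09e-10). Nnt, partly deleted in C57BL/6J, stood at 20.1 ± 0.795 and 17.1 ± 1.71 CPM (SD, n = 4) and did not pass (edgeR adjusted p = 0.0926).

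Reads of the pseudogene Rps13-ps1 followed Xist across the libraries labelled WT. Per 100 Xist reads there were 1.07, 1.03, 1.06 and 1.00 Rps13-ps1 reads in replicates 1 to 4, with exact 95% counting intervals that all overlap, from 0.982 to 1.17 in replicate 1 and from 0.81 to 1.37 in replicate 3. RP23-71I22.5 did not follow Xist, with 99, 39, 53 and 82 reads in the same libraries.

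Called genes lay next to each other in the genome more often than chance gives, with 358 neighbouring pairs of called genes against a median of 322 over 10000 permutations (permutation p = 0.012). The DNA around C3 alone does not account for this excess, because without genes within 10 Mb of C3 there were 353 pairs against a median of 317 and a 95% range of 288 to 348 (permutation p = 0.013). A candidate explanation is that stretches of DNA elsewhere differ between the labelled groups. Shared regulation of neighbours, or copies of 1 gene family side by side, would give the same excess and was not tested.

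Among called genes annotated as long non-coding RNAs 41 were higher and 12 lower in the libraries labelled C3 KO, or 77.4% higher, against 57.9% of called protein-coding genes (2-sided Fisher exact p = 0.00448). By this test a shift of all called genes alike does not account for that share of 77.4%. The test treats genes as independent, although they were measured in the same libraries and neighbours can rise together. Its p-value therefore does not measure the spread between libraries. Malat1 and Snhg11 were chosen after their values were seen. Malat1 was 1.29-fold higher and Snhg11, which the annotation lists as protein-coding, 1.97-fold higher. An effect of the genotype on this class cannot be separated from the other differences between the labels.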
